A study of Homo sapiens with 120 samples.

How the data were processed

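Total RNA of 120 TK6 cultures was hybridized to Affymetrix HG-U133 Plus 2 arrays, with 3 arrays in each of 40 groups of chemical, dose and time, per the labels. The deposited values are log2 expression values per probe set made with RMA, per the submitters' processing notes. The version and software of RMA, and whether all arrays were normalized together, are not stated. The table held 54675 probe sets, of which 62 are Affymetrix controls, and each array's median lay between 6.133 and 6.243. No 2 arrays were identical, and the highest correlation between 2 arrays was 0.99835 over all probe sets. Over the tested genes the highest between arrays of different groups was 0.99878.

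Genes were taken from the platform's table of probe sets: 41091 probe sets named 1 gene symbol, 1801 named several and 11721 listed none, and those without a single symbol were left out. Of the first, 41037 had an identifier in the RefSeq table of genome build GRCh38.p14, and 0 symbols were updated. Each of the 19775 genes was represented by its probe set with the highest mean, and 10523 genes had 2 or more. Genes were tested if at least 3 arrays reached 6.183, the median over probe sets of their mean log2 values, which left 14023. Genes of the fixed lists without a single-symbol probe set, or below that limit, were not analysed here. No genome was given, so positions are not reported, and gene length is that of the RefSeq table.

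Linear models were fitted in limma 3.58.1 in R 4.3.3, with the package data.table (version 1.17.8). Each chemical's 24 arrays formed one fit with 8 group means and no block. Differences between chemicals used the 48 arrays of both sets, and the class comparison used the 96 arrays of MMS, EMS, colcemid and vincristine. Moderated two-sided tests were adjusted by Benjamini and Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. There were 30 dose comparisons, 5 between times, 12 between chemicals, 2 between classes and 2 among untreated sets. Correlations are across genes, without a p-value. Between chemicals they use changes averaged over experiments, with the SD over pairs of single experiments. Over the class genes they are means over single formaldehyde experiments, with their SD. The limma camera test compared each list with all other tested genes, with the preset correlation between genes and then with an estimated one, adjusted over the lists with at least 5 tested genes and the 10 highest-dose comparisons. Checks and figures used python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

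The comparisons, tests, lists and rule for named genes were set before the data were examined. Named genes are the called genes with the largest changes that went the same way in all 3 experiments (10 each way for formaldehyde, 8 for the others), up to 4 called genes of each list, a fixed panel, and the 5 largest differences each way between the paired chemicals. The panel was CDKN1A, MDM2, GADD45A, HSPA1A, HMOX1, ATF3, CCNB1, TUBB, TUBA1A and ADH5, and HSPA1A had no probe set of its own. For the paired chemicals GDF15 and PCNA were added to it, outside the rule. The 26 lists were p53 targets, heat shock and chaperones, NRF2 and thiol defence, metallothioneins, formaldehyde metabolism, Fanconi and crosslink repair, excision repair and direct reversal, ATF4 and amino acid response, unfolded protein response, mitosis, DNA replication, histones and tubulins, then immediate early genes, NF-kappaB targets, interferon response, cholesterol synthesis, hypoxia and glycolysis, B cell identity, plasma cell differentiation, apoptosis regulators, housekeeping, and markers of T and NK cells, monocytes and granulocytes, epithelium and fibroblasts, and red blood cells. They were written from general knowledge, and some genes stand in more than 1 list.

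The labels number the arrays of each set as experiments 1 to 3, which was taken to pair treated and untreated arrays. As a check, deviations from the group means of arrays with the same number correlated, in the mean over pairs, above 0 in 29 of 30 comparisons (median 0.2855, range -0.132 to 0.509, against -0.141 for other numbers), and every pair lay over 0.1 in 19. The alternatives were experiment as a block, no filter on dim genes, the mean of probe sets (12384 genes), quantile normalization repeated (13977 genes), all arrays in one fit, each experiment left out, GAPDH in place of ACTB and an estimated correlation within lists. Others were added after seeing the data: leaving out the untreated formaldehyde array of experiment 3 at 4 h, class genes moved in opposite directions, and gene length within 5 bands of brightness. The median change of all genes lay between -0.039 and 0.0785 in the 30 comparisons, and between -0.0491 and 0.0897 with quantile normalization repeated.

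The models were tested on simulated data for 14023 genes, with 100 genes changed at each of 2 sizes. For 4 h of 200 µM formaldehyde 97% of changes of 0.5 log2 and 100% of changes of 1 log2 were called, with 9 calls on unchanged genes. Of changes of 0.5 log2, 68% were called for the difference between times with formaldehyde, 75% for that between formaldehyde and MMS at 4 h and 93% for the classes at 24 h. Of 27 comparisons simulated without change, 1 gave any call. The simulated noise was independent between genes and arrays, without deviations shared within an experiment, so these rates may be better than those in the real data.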

Results

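The series holds 120 gene expression arrays of TK6, an established human lymphoblastoid (B cell) line, after 4 h or 24 h with 1 of 5 chemicals or without treatment. Formaldehyde (FA), an aldehyde that crosslinks DNA and proteins, was given at 50, 100 and 200 µM. Methyl methanesulfonate (MMS) at 80, 160 and 320 µM and ethyl methanesulfonate (EMS) at 1, 2 and 4 mM are alkylating agents that break chromosomes, here called clastogens. Colcemid (COL) and vincristine (VCR) bind tubulin and disturb the sharing out of chromosomes, and are called aneugens here. The labels give the colcemid and vincristine doses as 1, 2 and 4 µg/ml, with leading zeros in the titles that leave open whether a decimal point was lost, so these are called the lowest, middle and highest labelled dose. Each chemical had its own untreated arrays at both times, and each of the 40 groups held 3 arrays, labelled as experiments 1 to 3. The 5 sets are treated as separate sets of experiments, as the labels number them, and p-values measure the spread between experiments. Of 19775 genes with a probe set, 14023 were bright enough to be tested. Signals are on a log2 scale, changes are treated minus untreated with their standard error (SE, n = 3 arrays per group), and all adjusted p-values are from limma. The number of arrays limits the precision of every value.

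**Figure D1:**
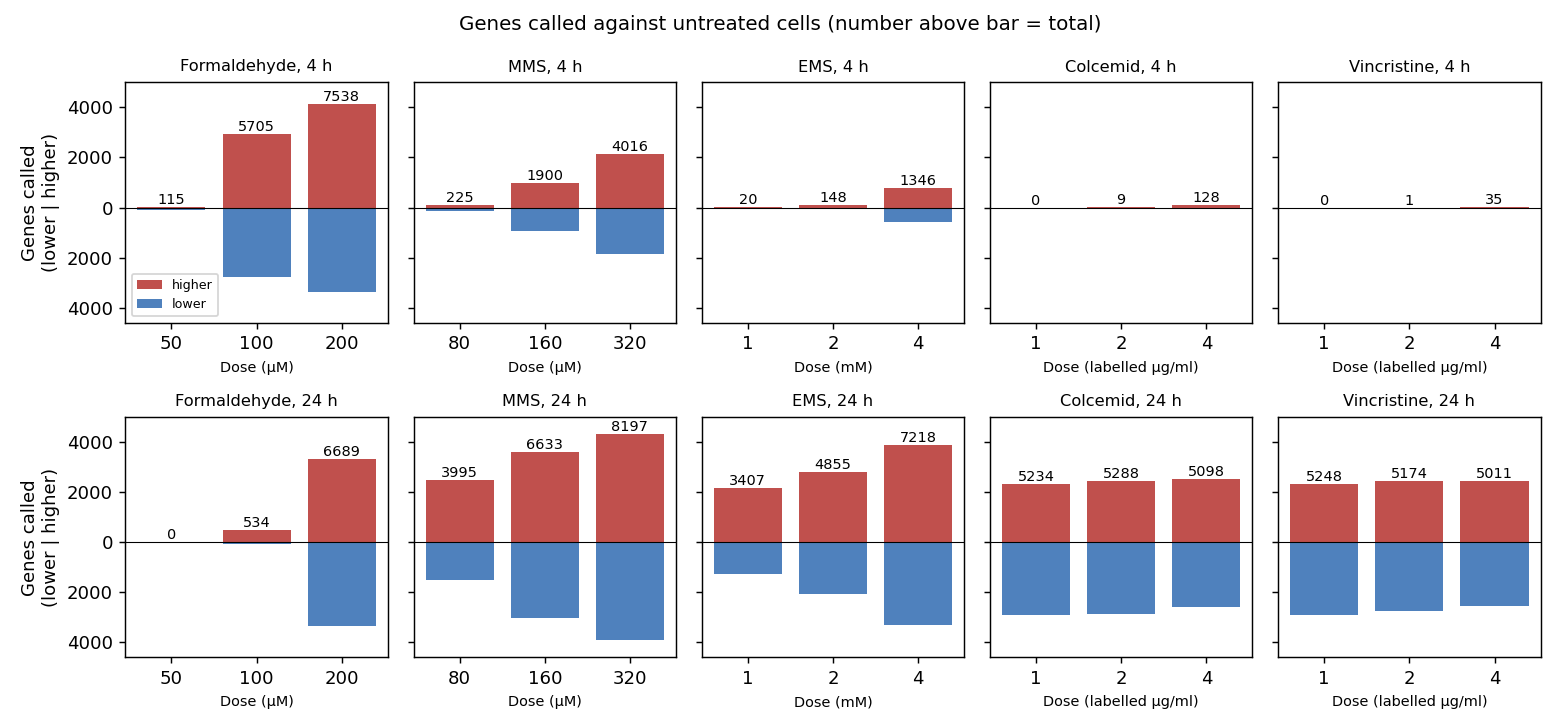
Number of genes called higher (red, upward) and lower (blue, downward) than in untreated cells for each chemical, dose and time, with the total above each bar. The highest count at 4 h was 7538 with formaldehyde, and colcemid and vincristine gave 5011 to 5288 genes at 24 h; their doses are the labelled values, whose scale is in doubt.

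The first question was which genes formaldehyde changed early. After 4 h of 200 µM, ARRDC3, which encodes an arrestin-like adaptor protein, rose 8.7-fold (log2 change 3.12 ± 0.12, adjusted p = 6.35e-15), from a mean log2 signal of 6.16 ± 0.156 (SD) to 9.28 ± 0.083. CCNG2, an atypical cyclin linked to growth arrest, rose by 2.97 ± 0.14, ATF3, a stress-induced transcription factor, by 2.89 ± 0.15, and DNAJB4, a co-chaperone, by 2.29 ± 0.086. The deepest falls were those of RORA, a nuclear receptor (-3.51 ± 0.11, adjusted p = 2.65e-16), ST8SIA4, a sialyltransferase (-3.37 ± 0.094), CPEB2, which binds RNA (-3.29 ± 0.086), and ZEB2, a transcriptional repressor (-2.84 ± 0.13). In all, 7538 genes were called, 4147 higher and 3391 lower, but 585 fell at least 2-fold and 52 rose as much. At 100 µM 5705 genes were called, 2926 higher and 2779 lower, with 40 at least 2-fold higher and 278 lower (3737 to 5286 called with 1 experiment left out). At 50 µM 115 genes were called, 30 higher and 85 lower. That count was 261 with experiment as a block and 25 without the untreated array of experiment 3, and it lay between 1 and 7 when a whole experiment was left out.

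The p53 targets, genes switched on by the tumour suppressor p53 after DNA damage, split at 4 h of 200 µM: 14 of 41 rose, 15 fell and 12 were not called. Adjusted over the list alone, 15 rose and 15 fell. MDM2, which encodes the protein that removes p53, fell by 0.96 on the log2 scale (SE 0.084, adjusted p = 3.74e-09), and PPM1D, a phosphatase of the same pathway, changed by -0.98 ± 0.15. SERTAD1 (1.46), the stress cytokine GDF15 (1.38), the growth arrest gene GADD45A (0.71) and the cell cycle inhibitor CDKN1A (0.21 ± 0.064) rose. At 100 µM, however, 33 of the 41 rose and 2 fell, among them CDKN1A (1.00), MDM2 (0.50), PPM1D (1.44) and GDF15 (2.33), and at 50 µM 3 rose. The direct comparison of 200 with 100 µM, made after the values were seen, found 32 of the 41 lower and 1 higher at 200 µM, against 2450 lower and 2438 higher over all tested genes. The difference was -1.46 (SE 0.084) for MDM2, -2.42 (SE 0.15) for PPM1D, -1.69 (SE 0.098) for SESN2, a stress sensor, and -0.79 (SE 0.064) for CDKN1A. The camera test of the list at 200 µM gave an adjusted p of 0.914, with a median change of 0.05 and a mean of the opposite sign.

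Heat shock and chaperone genes rose at 4 h of 200 µM: 13 of 20 rose and none fell (14 and 0 adjusted over the list alone, camera adjusted p = 0.000108), led by DNAJB4, CHORDC1 (0.72), DEDD2 (0.62) and HSPB1 (0.57). Of 18 immediate early genes, which respond first to many stimuli, 12 rose and 3 fell, with JUN at 2.28, EGR1 at 2.09 and FOS at 1.83 (camera adjusted p = 0.00111, adjusted p = 0.178 with an estimated correlation). Mitosis genes fell: 18 of 30 fell and none rose (21 fell and 1 rose adjusted over the list alone), including the kinesin KIF23 (-1.23), CENPE (-0.94) and the kinase AURKA (-0.92). Their camera adjusted p was 1.67e-05, and adjusted p = 0.325 with an estimated correlation. Of 18 Fanconi and crosslink repair genes 10 fell and 4 rose (10 and 5 adjusted over the list alone, camera adjusted p = 0.0516), with FANCM at -1.41, FANCF at -1.31 and PALB2 at -1.17. In cholesterol synthesis 10 of 15 genes rose and 1 fell (11 and 1 adjusted over the list alone, camera adjusted p = 0.0717, adjusted p = 0.686 with an estimated correlation, and adjusted p = 0.0407 with experiment as a block). Of 15 apoptosis regulators 6 rose and 5 fell, with BCL2 at -1.34 (camera adjusted p = 0.549), and of 9 plasma cell genes 1 rose and 4 fell, with IRF4 at -1.52 (camera adjusted p = 0.252). Among 9 genes of formaldehyde metabolism 3 rose and none fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.314), and ADH5, the main enzyme of formaldehyde oxidation, was not called (0.10 ± 0.044). The ATF4, NF-kappaB and DNA replication lists were divided, with 9 genes higher and 10 lower of 24, 5 higher and 7 lower of 17, and 9 higher and 8 lower of 27, and in each the median and the mean differed in sign.

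After 24 h of 200 µM the p53 targets rose together: 38 of 41 rose and none fell, with a median log2 change of 1.45 (camera adjusted p = 6.41e-30, adjusted p = 0.00151 with an estimated correlation). GDF15 rose 16.8-fold (4.07 ± 0.13), and TP53I3 (3.39), TP53INP1 (3.39), GADD45A (2.30), MDM2 (1.97 ± 0.084) and CDKN1A (1.93 ± 0.064) rose with it. The largest rise among the 14023 genes that met the rule for naming was that of CYP4F3, a lipid-oxidizing cytochrome (5.58 ± 0.10, adjusted p = 1.72e-19), followed by FAM13C (4.85) and the lysosomal enzyme FUCA1 (4.12). IGHM, the heavy chain of immunoglobulin M, fell most (-2.90 ± 0.11), then the adhesion molecule CHL1 (-2.45). Counts were 6689 genes at 200 µM (3342 higher, 3347 lower, 361 and 113 of them at least 2-fold) and 534 at 100 µM (480 higher, 54 lower). The latter count was 840 with experiment as a block, 1142 with all arrays in one fit and 157 to 201 with 1 experiment left out. At 50 µM limma called 0 genes, with 385 at an unadjusted p under 0.05, and 1 gene was called with all arrays in one fit. At 100 µM 29 of the 41 p53 targets rose and none fell, and at 50 µM none was called.

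Cholesterol synthesis genes fell at 24 h of 200 µM, with 14 of 15 lower and none higher, among them HMGCS1 (-1.65), DHCR7 (-1.18) and SQLE (-1.17) (camera adjusted p = 3.63e-09, adjusted p = 0.0902 with an estimated correlation). Of 18 hypoxia and glycolysis genes 14 fell and none rose, including PFKFB4 (-1.73) and HK2 (-1.20) (camera adjusted p = 6.31e-06, adjusted p = 0.203 with an estimated correlation). Among NF-kappaB targets, genes of inflammatory signalling, 14 of 17 rose and none fell (15 and 0 adjusted over the list alone), with TNFAIP3 at 1.16 and ICAM1 at 1.01 (camera adjusted p = 1.9e-06, adjusted p = 0.0649 with an estimated correlation). Histone genes rose, 9 of 13 with 1 lower, led by H2BC12 (2.33) and H2AC6 (1.40) (camera adjusted p = 0.000283, adjusted p = 0.0239 with an estimated correlation). Of 24 ATF4 and amino acid response genes 17 rose and 4 fell (18 and 4 adjusted over the list alone), with ATF3 at 3.21, SESN2 at 2.60 and DDIT3 at 2.35 (camera adjusted p = 1.19e-05, adjusted p = 0.11 with an estimated correlation). Apoptosis regulators rose in 11 of 15 cases with 1 lower, among them APAF1 (1.61) and PMAIP1 (1.04) (camera adjusted p = 9.79e-05, adjusted p = 0.0488 with an estimated correlation). Mitosis genes were lower, with 18 of 30 fallen and 3 risen, including BUB1 (-1.10) and CCNB1 (-1.06) (camera adjusted p = 3.82e-05, adjusted p = 0.359 with an estimated correlation). Of 9 formaldehyde metabolism genes 6 fell and 1 rose, with FTO, an RNA demethylase that releases formaldehyde, at -1.01 (camera adjusted p = 0.0142, adjusted p = 0.0904 with an estimated correlation). Heat shock genes were divided, 7 higher and 9 lower of 20, with a median and mean of opposite sign. Metallothioneins are metal-binding proteins, and their list also holds the zinc exporter SLC30A1. Genes of this list rose in 7 of 8 cases (7 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00364, adjusted p = 0.104 with an estimated correlation). In the same arrays the log2 difference between the 3' and 5' control probe sets of ACTB, a measure of RNA quality, was 0.768 ± 0.0696 (SD) against 0.481 ± 0.0239 in untreated cells.

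**Figure D2:**
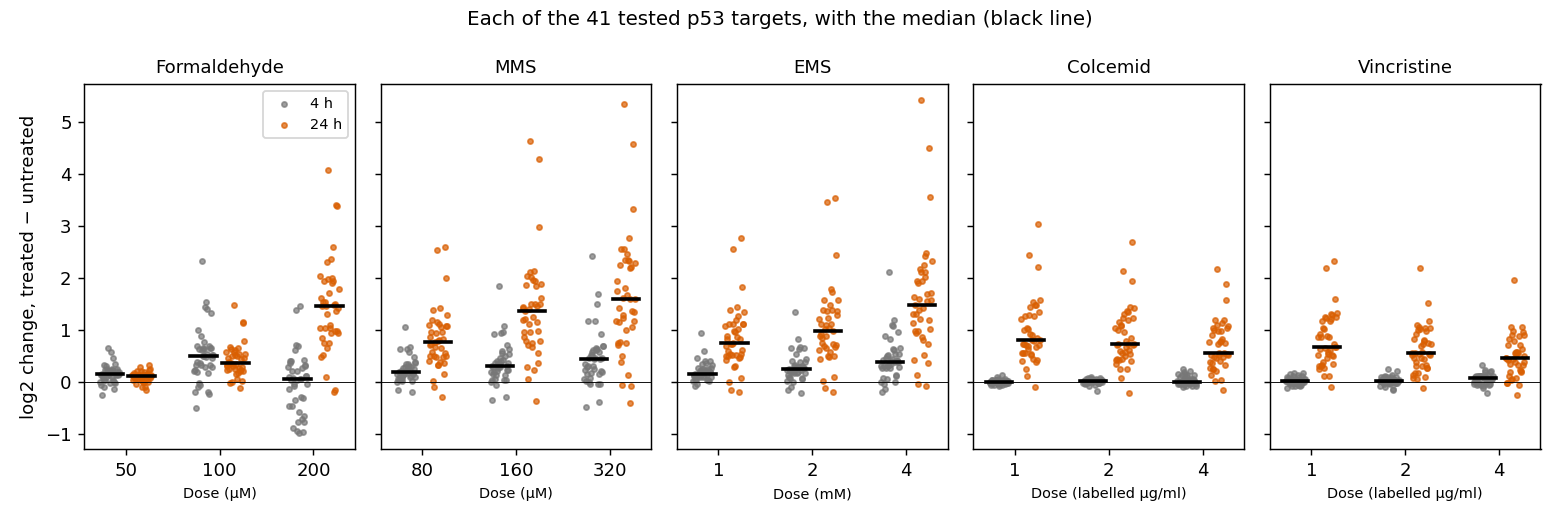
Log2 change against untreated cells of each of the 41 tested p53 targets (points) at 4 h (grey) and 24 h (orange) for each dose, with the median as a black line. At 4 h the formaldehyde medians were 0.14, 0.50 and 0.05 at 50, 100 and 200 µM, and at 24 h the highest was 1.45 at 200 µM; colcemid and vincristine doses are the labelled values.

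Between 4 h and 24 h of 200 µM formaldehyde the change differed for 7477 genes, 3620 higher and 3857 lower at 24 h. MDM2 turned from -0.96 to 1.97, a difference of 2.93 (SE 0.12, adjusted p = 3.39e-14), and HMOX1, a heme-degrading enzyme of the oxidative stress response, turned from 0.59 to -0.33, a difference of -0.92 (SE 0.16, adjusted p = 3.73e-05). Of the p53 targets 38 of 41 were higher at 24 h than at 4 h and 1 was lower, of the heat shock genes 2 of 20 were higher and 14 lower, and of the cholesterol synthesis genes 15 of 15 were lower. With the difference called, 1070 genes were lower at 4 h and higher at 24 h than in untreated cells, and 898 the reverse. Of the 585 genes at least 2-fold lower at 4 h, 167 were still lower at 24 h, 193 were higher and 225 were not called.

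MMS raised stress genes within 4 h. At 320 µM HMOX1 rose 6.49-fold (2.70 ± 0.091, adjusted p = 5e-15), followed by INHBE, an inhibin subunit (2.68 ± 0.076), the hormone STC2 (2.50), ATF3 (2.45) and CTH, an enzyme of cysteine synthesis (2.39). The chemokine CCL2 (-1.86 ± 0.089) and PHLDA1 (-1.66) fell most. The ATF4 and amino acid response rose in 21 of 24 genes with 1 lower, at a median of 0.84 (camera adjusted p = 3.46e-26). Of the p53 targets 30 of 41 rose and 2 fell (32 and 2 adjusted over the list alone, camera adjusted p = 2.13e-16), with GDF15 at 2.42, SESN2 at 1.69, CDKN1A at 1.16 ± 0.047 and MDM2 at 0.30 ± 0.096. Heat shock genes rose in 10 of 20 cases (10 higher and 1 lower adjusted over the list alone, camera adjusted p = 2.21e-05), led by DNAJB4 (1.93), HSPA6 (1.89) and BAG3 (1.39). NRF2 and thiol defence genes rose in 14 of 20 cases with 1 lower (15 and 2 adjusted over the list alone, camera adjusted p = 7.77e-08), with SRXN1 at 1.00 and SLC7A11 at 0.96. Mitosis genes fell in 24 of 30 cases with none higher (25 lower and 1 higher adjusted over the list alone, camera adjusted p = 4.9e-16), with CCNB1 at -0.98. Replication genes rose in 19 of 27 with 1 lower (21 and 1 adjusted over the list alone, camera adjusted p = 2.21e-08), with CDC6 at 0.84. All 6 of these list calls held with an estimated correlation, at adjusted p between 0.00151 and 0.0443. NF-kappaB targets fell in 11 of 17 cases with 1 higher (camera adjusted p = 2.02e-05, adjusted p = 0.192 with an estimated correlation). Counts were 225, 1900 and 4016 genes at 80, 160 and 320 µM, of which 87, 978 and 2142 were higher. The first was 385 with experiment as a block, 140 without the filter, 461 with quantile normalization repeated and 442 with all arrays in one fit. With 1 experiment left out the 3 counts were 21 to 51, 556 to 1134 and 2377 to 3189.

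At 24 h of 320 µM MMS, CYP4F3 (5.89 ± 0.11), the heat shock protein gene HSPA6 (5.85 ± 0.10) and GDF15 (5.34 ± 0.060) rose most, and the glycolytic enzyme HK2 (-2.77 ± 0.061) and the globin HBD (-2.54 ± 0.095) fell most. Of the p53 targets 37 of 41 rose and 1 fell, at a median of 1.58 (camera adjusted p = 3.02e-21), with TP53I3 at 4.56, MDM2 at 2.33 and CDKN1A at 2.25. DNA replication genes rose in 24 of 27 cases with 1 lower (camera adjusted p = 7.52e-08), among them TK1 (2.03) and CDT1 (1.51). Both calls held with an estimated correlation, at adjusted p = 0.0101 and 0.038. Fanconi genes rose in 14 of 18 cases with 2 lower (15 and 2 adjusted over the list alone, camera adjusted p = 0.000576, adjusted p = 0.218 with an estimated correlation), led by BRIP1 (2.04). Cholesterol synthesis genes fell in 13 of 15 cases (camera adjusted p = 2e-06, adjusted p = 0.0675 with an estimated correlation), with SQLE at -1.91. Hypoxia and glycolysis genes fell in 12 of 18 with 2 higher (camera adjusted p = 0.00012, adjusted p = 0.216 with an estimated correlation). B cell identity genes fell in 14 of 17 with 1 higher (camera adjusted p = 0.000576, adjusted p = 0.138 with an estimated correlation), among them FCER2 (-1.22) and CD22 (-1.01). Histones rose in 10 of 13 with 2 lower (camera adjusted p = 0.032, adjusted p = 0.503 with an estimated correlation). ATF4 targets rose in 12 of 24 with 5 lower (camera adjusted p = 0.0103, adjusted p = 0.359 with an estimated correlation). Plasma cell genes fell in 4 of 9 with 1 higher (camera adjusted p = 0.0359, adjusted p = 0.371 with an estimated correlation), with MZB1 at -2.05. Counts were 3995 (1954 to 2940 with 1 experiment left out), 6633 and 8197 genes at 80, 160 and 320 µM, of which 2469, 3605 and 4313 were higher. At 320 µM the higher share was 52.6%, and 48.6% with quantile normalization repeated. The ACTB 3' minus 5' difference was 1.06 ± 0.123 (SD), 1.28 ± 0.00819 and 1.88 ± 0.26 at the 3 doses, against 0.942 ± 0.0793 in untreated cells. Whether RNA quality had a part in the gene groups just named stays open. The change differed between 24 h and 4 h for 6342 genes, 3583 higher and 2759 lower at 24 h, and for 37 p53 targets it was higher.

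EMS gave a similar but smaller set of changes at 4 h. At 4 mM GDF15 rose 4.33-fold (2.11 ± 0.059, adjusted p = 1.93e-15), ATF3 by 1.60 ± 0.067, CHAC1, which breaks down glutathione, by 1.37 ± 0.051 and CDKN1A by 0.89 ± 0.038, while PSRC1, a spindle protein (-0.80 ± 0.072), and CENPE (-0.79) fell most. Of the p53 targets 32 of 41 rose and 1 fell (33 and 1 adjusted over the list alone, camera adjusted p = 1.41e-43). Of the ATF4 list 19 of 24 rose and none fell (21 and 1 adjusted over the list alone, camera adjusted p = 2.29e-30). Of the replication list 14 of 27 rose and none fell (18 and 1 adjusted over the list alone, camera adjusted p = 3.92e-12). Mitosis genes fell in 21 of 30 cases with none higher (24 lower adjusted over the list alone, camera adjusted p = 2.61e-27). Immediate early genes rose in 6 of 18 cases with 1 lower (9 and 1 adjusted over the list alone, camera adjusted p = 2.82e-05), and metallothionein list genes in 3 of 8, led by the zinc exporter SLC30A1 at 0.88 (camera adjusted p = 0.000482). These 6 calls held with an estimated correlation, at adjusted p between 0.00151 and 0.0239, whereas that of heat shock genes, 4 of 20 higher (5 adjusted over the list alone, camera adjusted p = 0.0179), gave adjusted p = 0.198 with an estimated correlation. NRF2 and thiol defence genes rose in 6 of 20 with 1 lower (8 and 1 adjusted over the list alone, camera adjusted p = 1.26e-05, adjusted p = 0.156 with an estimated correlation). Counts were 20, 148 and 1346 genes at 1, 2 and 4 mM, with 15, 101 and 778 higher, and 47 genes at 1 mM with experiment as a block. With quantile normalization repeated the 3 counts were 66, 320 and 2062, and with 1 experiment left out 3, 23 to 36 and 463 to 560.

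At 24 h of 4 mM EMS, GDF15 (5.41 ± 0.059), CYP4F3 (4.91 ± 0.12), FAM13C (4.76) and TP53I3 (4.48) rose most, and HBD (-2.09 ± 0.11), HK2 (-2.07) and the neuritin gene NRN1 (-1.91) fell most. All 38 called p53 targets of 41 tested rose, at a median of 1.47 (camera adjusted p = 3.6e-28, adjusted p = 0.005 with an estimated correlation), with CDKN1A at 1.93 ± 0.038 and MDM2 at 2.11 ± 0.067. Cholesterol synthesis genes fell in 13 of 15 cases with 1 higher (camera adjusted p = 3.89e-08, adjusted p = 0.0101 with an estimated correlation), led by HMGCS1 (-1.74). Hypoxia genes fell in 13 of 18 with 1 higher (camera adjusted p = 9.95e-06, adjusted p = 0.172 with an estimated correlation). The ATF4 list rose in 17 of 24 with 4 lower (camera adjusted p = 2.33e-06, adjusted p = 0.178 with an estimated correlation). Replication genes rose in 15 of 27 with 3 lower (16 and 3 adjusted over the list alone, camera adjusted p = 0.00847, adjusted p = 0.38 with an estimated correlation), and interferon response genes rose in 10 of 17, with IFIT2 at 1.29 (camera adjusted p = 0.00982, adjusted p = 0.689 with an estimated correlation). Mitosis genes were divided, 9 higher and 13 lower of 30 (10 and 14 adjusted over the list alone), with a median and mean of opposite sign. Counts were 3407 (1826 to 2265 with 1 experiment left out), 4855 and 7218 genes at 1, 2 and 4 mM, of which 2154, 2792 and 3903 were higher. The ACTB 3' minus 5' difference was 0.664 ± 0.0342 (SD) at 4 mM against 0.521 ± 0.0715 in untreated cells, each treated array lying above each untreated one. Whether RNA quality had a part in these gene groups stays open. The change differed between 24 h and 4 h for 5373 genes, 2999 higher and 2374 lower at 24 h.

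MMS and EMS differ in structure by a methyl against an ethyl group, and their highest doses, 320 µM and 4 mM, were not matched. At 4 h the changes differed for 1029 genes (341 to 510 with 1 experiment left out, 1587 with quantile normalization repeated). HMOX1 rose by 2.70 with MMS and 0.52 with EMS, a difference of 2.18 (95% interval 1.95 to 2.41, adjusted p = 3.04e-16), and HSPA6 differed by 1.71 (1.45 to 1.96). The changes of CCL2 and PHLDA1 differed by -1.31 and -1.27, being lower with MMS. No difference was called for MDM2 at 4 h, -0.02 (-0.27 to 0.22), or GADD45A, 0.05 (-0.06 to 0.17), whereas CDKN1A rose more with MMS by 0.27 (0.16 to 0.38, adjusted p = 0.000956). At 24 h the changes differed for 3780 genes (2208 to 3263 with 1 experiment left out), led by HSPA6, 5.85 with MMS and 0.55 with EMS, a difference of 5.30 (5.05 to 5.55, adjusted p = 1.95e-28). The interferon-induced genes IFI44L and IFIT1 differed by -1.64 (-2.46 to -0.83) and -1.59 (-2.28 to -0.89), with mean changes above 0 for EMS and below 0 for MMS. The difference at 24 h was not called for GDF15, -0.07 (-0.24 to 0.10), or MDM2, 0.22 (-0.02 to 0.47). Across genes, which are not independent replicates, the changes correlated at r = 0.736 ± 0.0333 (SD over pairs of single experiments) at 4 h and 0.882 ± 0.0135 at 24 h. These r are of changes averaged over experiments. Single pairs gave lower values, 0.497 to 0.603 at 4 h and 0.813 to 0.854 at 24 h. The pairs share experiments, so their SD is not an error of r.

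Colcemid at 4 h lowered tubulin genes and raised early response genes. At the highest labelled dose 4 of 12 tubulin genes fell and none rose (7 and 0 adjusted over the list alone, camera adjusted p = 6.64e-13), namely TUBA4A (-0.33 ± 0.035), TUBB4B (-0.26), TUBB3 (-0.26) and TUBB (-0.18 ± 0.032). IFFO2 (1.16 ± 0.073, adjusted p = 5.26e-09), the transcription factor KLF6 (1.06 ± 0.057), ANTXR2, a receptor for collagen VI (1.00), the activation marker CD69 (0.99) and the chemokine CXCL8 (0.92) rose. Of immediate early genes 6 of 18 rose (9 adjusted over the list alone, camera adjusted p = 4.78e-21) and of NF-kappaB targets 6 of 17 (11 adjusted over the list alone, camera adjusted p = 1.79e-16), with TNF at 0.49, and none fell in either list. Plasma cell genes fell in 2 of 9 cases, TNFRSF17 (-0.45) and IRF4 (-0.22) (camera adjusted p = 0.000359), and apoptosis regulators rose in 2 of 15, MCL1 (0.30) and BCL2 (0.30) (3 adjusted over the list alone, camera adjusted p = 4.76e-07). With an estimated correlation these 5 calls held, at adjusted p between 0.00325 and 0.0239. CDKN1A (-0.02 ± 0.042) and MDM2 (-0.08 ± 0.055) were not called, and of the p53 targets FAS (0.24) alone was called of 41. The highest labelled dose gave 128 genes, 113 higher and 15 lower. The count was 278 with experiment as a block, 239 with quantile normalization repeated, 83 with the mean of probe sets and 22 to 51 with 1 experiment left out. In these arrays the ACTB 3' minus 5' difference was 0.384 ± 0.00401 (SD) against 0.329 ± 0.0284 in untreated cells, each treated array above each untreated one. With the GAPDH control probe sets it went the other way, 0.121 ± 0.0191 against 0.14 ± 0.0193. Whether RNA quality had a part in these gene groups stays open. The share of higher genes was 88.3% and, with quantile normalization repeated, 77.4%. The middle dose gave 9 genes (0 to 2 with 1 experiment left out) and the lowest 0 in limma, with 265 at an unadjusted p under 0.05, and 0 in each alternative run.

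After 24 h of colcemid the p53 targets rose in 37 of 41 cases with none lower (38 adjusted over the list alone, median 0.55, camera adjusted p = 1.65e-28), with CDKN1A at 1.04 ± 0.042, MDM2 at 0.98 ± 0.055 and GDF15 at 2.16 ± 0.081. CYP4F3 (4.30 ± 0.11), the histone gene H2AC6 (2.77 ± 0.098) and RRAD, a small GTPase (2.47), rose most, and IGHM (-1.78 ± 0.14), TNFRSF17 (-1.73) and FBXO5, an inhibitor of the anaphase-promoting complex (-1.51), were among the 8 deepest falls. DNA replication genes fell in 25 of 27 cases with none higher (camera adjusted p = 7.25e-20), led by CCNE2 (-1.01). NF-kappaB targets rose in 16 of 17 cases (camera adjusted p = 2.26e-14), with CCL4 at 1.86 and TNF at 1.24. Immediate early genes rose in 15 of 18 with 1 lower (camera adjusted p = 2.21e-09), metallothionein list genes in 7 of 8 (camera adjusted p = 6.26e-08) and apoptosis regulators in 11 of 15 with 1 lower (camera adjusted p = 4.39e-05), and plasma cell genes fell in 5 of 9 with 1 higher (camera adjusted p = 0.00762). These 7 calls held with an estimated correlation, at adjusted p between 0.00358 and 0.0442. Tubulin genes fell in 7 of 12 with 2 higher (camera adjusted p = 0.000233, adjusted p = 0.0649 with an estimated correlation), with TUBB at -1.07 ± 0.032, while TUBA1A rose by 0.84. Histones rose in 10 of 13 with 2 lower (10 and 3 adjusted over the list alone, camera adjusted p = 1.43e-06, adjusted p = 0.0649 with an estimated correlation). Interferon genes rose in 13 of 17 (14 adjusted over the list alone, camera adjusted p = 1.85e-07, adjusted p = 0.156 with an estimated correlation). Hypoxia genes fell in 12 of 18 with 1 higher (camera adjusted p = 2.99e-06, adjusted p = 0.0525 with an estimated correlation). From the lowest to the highest labelled dose 5234, 5288 and 5098 genes were called, of which 2329, 2436 and 2531 were higher, or 44.5%, 46.1% and 49.6%, against 48.5%, 50.9% and 50.5% with quantile normalization repeated. The change differed between 24 h and 4 h for 3155 genes, 1474 higher and 1681 lower at 24 h (1721 to 2064 with 1 experiment left out).

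Vincristine at 4 h also lowered tubulin genes: 3 of 12 fell at the highest labelled dose and none rose (7 and 0 adjusted over the list alone, camera adjusted p = 2.7e-11, adjusted p = 0.00535 with an estimated correlation), namely TUBB2A (-0.30 ± 0.042), TUBB3 (-0.29 ± 0.055) and TUBA4A (-0.25). SOCS3, an inhibitor of cytokine signalling (0.67 ± 0.095, adjusted p = 0.00326), CD69 (0.61) and RGS1 (0.57) rose most, and UPP1, a uridine phosphorylase (-0.41 ± 0.057), and TNFRSF17 (-0.36) fell most. Immediate early genes rose in 3 of 18 cases (7 higher and 1 lower adjusted over the list alone, camera adjusted p = 2.74e-05, adjusted p = 0.104 with an estimated correlation). TNF (0.38) was the called one of 17 NF-kappaB targets (6 higher adjusted over the list alone, camera adjusted p = 5.05e-07, adjusted p = 0.157 with an estimated correlation). None of the 41 p53 targets was called (1 adjusted over the list alone, camera adjusted p = 0.0108 with a median of 0.07, adjusted p = 0.598 with an estimated correlation). The highest dose gave 35 genes, 26 higher and 9 lower, 110 with experiment as a block, 58 with all arrays in one fit, 53 with quantile normalization repeated and 21 with the mean of probe sets. The share of higher genes was 74.3% and, with quantile normalization repeated, 58.5%. The middle dose gave 1 gene, and 3 with the block, and the lowest gave 0 in limma, with 511 at an unadjusted p under 0.05, 1 with quantile normalization repeated and 2 with all arrays in one fit. Leaving out 1 experiment gave 0 to 7 genes at the highest dose.

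At 24 h of vincristine, 33 of 41 p53 targets rose and 1 fell (median 0.46, camera adjusted p = 3.28e-17), with CDKN1A at 0.81 ± 0.054 and MDM2 at 0.77 ± 0.058. CYP4F3 (3.15 ± 0.15), CXCL8 (2.52) and the cytokine IL6 (2.14) rose most, and TNFRSF17 (-2.24 ± 0.071), ERICH3 (-2.22) and the peptide hormone gene APELA (-2.04) fell most. Replication genes fell in 23 of 27 cases with none higher (camera adjusted p = 1.16e-14). NF-kappaB targets rose in 15 of 17 with none lower (camera adjusted p = 8.15e-16), metallothionein list genes rose in 6 of 8 (camera adjusted p = 1.43e-07) and plasma cell genes fell in 7 of 9 (camera adjusted p = 0.00012). These 5 calls, the p53 targets included, held with an estimated correlation, at adjusted p between 0.0041 and 0.0348. Tubulin genes fell in 7 of 12 with 2 higher (camera adjusted p = 0.0001, adjusted p = 0.0675 with an estimated correlation), with TUBB at -1.39 ± 0.039 and TUBA4A at -1.15. Histones rose in 9 of 13 with 1 lower (10 and 1 adjusted over the list alone, camera adjusted p = 0.000131, adjusted p = 0.192 with an estimated correlation). Hypoxia genes fell in 13 of 18 with 2 higher (camera adjusted p = 5.54e-07, adjusted p = 0.156 with an estimated correlation), and immediate early genes rose in 10 of 18 with 1 lower (camera adjusted p = 9.42e-05, adjusted p = 0.138 with an estimated correlation). From the lowest to the highest labelled dose 5248, 5174 and 5011 genes were called, of which 2331, 2438 and 2456 were higher, or 44.4%, 47.1% and 49.0%. With quantile normalization repeated the shares were 50.7%, 51.3% and 50.9%, so that the majority turned from lower to higher. The change differed between 24 h and 4 h for 3147 genes, 1409 higher and 1738 lower at 24 h (1656 to 2359 with 1 experiment left out).

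**Figure D3:**
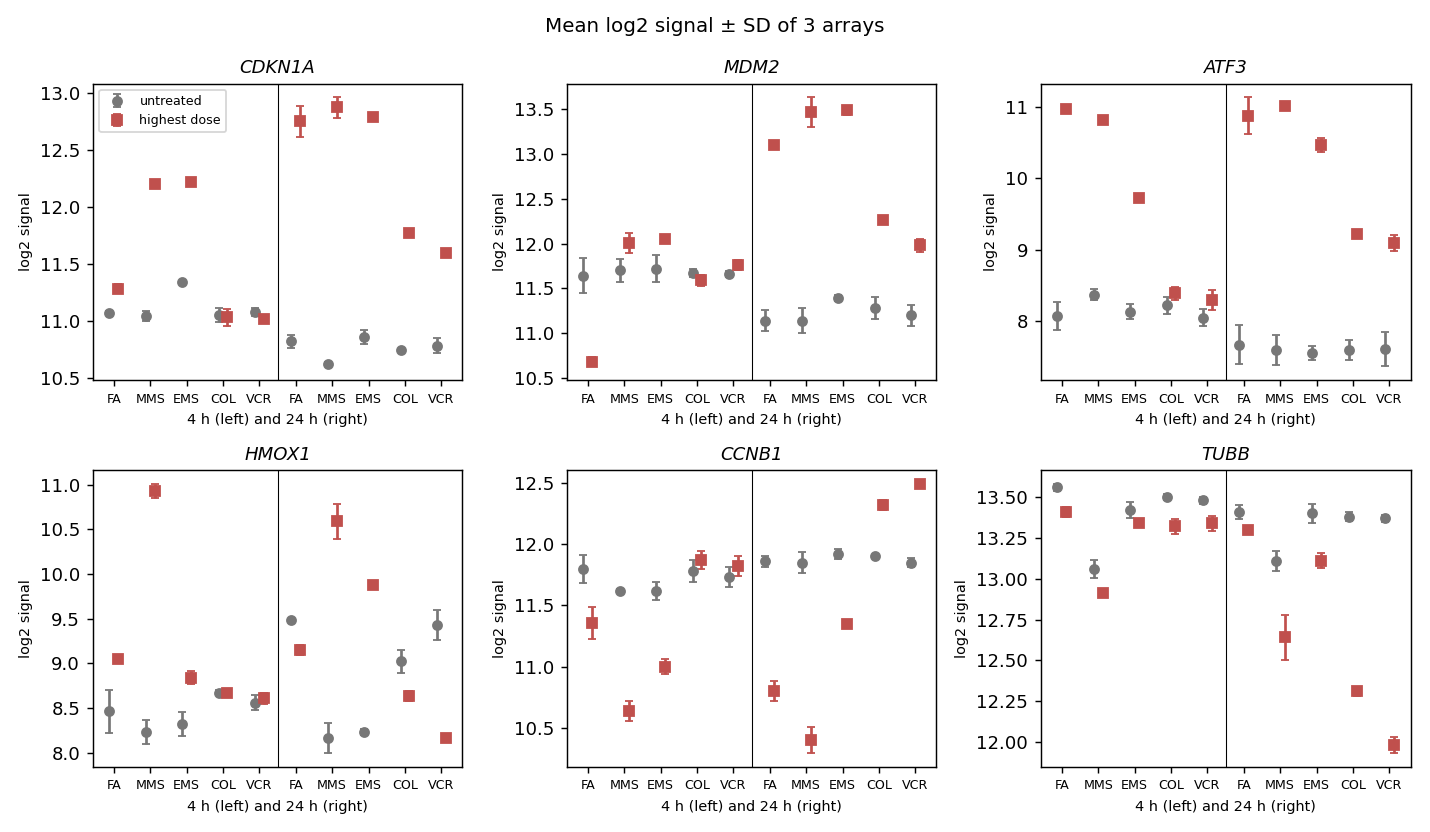
Mean log2 signal of 6 genes in untreated cells (grey circles) and at the highest dose (red squares) of each chemical at 4 h (left of the line) and 24 h (right), with bars for the SD of 3 arrays. MDM2 was below the untreated mean at 4 h of formaldehyde, by -0.96, and above it at 24 h of each chemical, and TUBB was lowest after 24 h of vincristine.

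Colcemid and vincristine, which are not structural analogs, differed in 8 genes at 4 h and 283 at 24 h, at highest labelled doses that bear the same figure but whose scale is in doubt. These counts were 20 and 588 with quantile normalization repeated and 4 to 6 and 93 to 106 with 1 experiment left out, and the second was 598 with experiment as a block. At 4 h ANTXR2 (1.01, 95% interval 0.78 to 1.25), IFFO2 (0.94, 0.73 to 1.15), TSC22D3, a glucocorticoid-induced gene (0.75, 0.58 to 0.92), and KLF6 (0.71, 0.53 to 0.90) were higher with colcemid. At 24 h RRAD (2.01, 1.65 to 2.37) and ANTXR2 (1.70, 1.46 to 1.93) were higher with colcemid and IL6 was lower (-0.67). No difference was called for CDKN1A at 24 h, 0.22 (0.09 to 0.36, adjusted p = 0.0728). The changes, averaged over experiments, correlated across genes at r = 0.310 ± 0.148 (SD over pairs of single experiments) at 4 h and 0.881 ± 0.0261 at 24 h. Single pairs gave -0.109 to 0.392 at 4 h and 0.738 to 0.818 at 24 h.

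**Figure D4:**
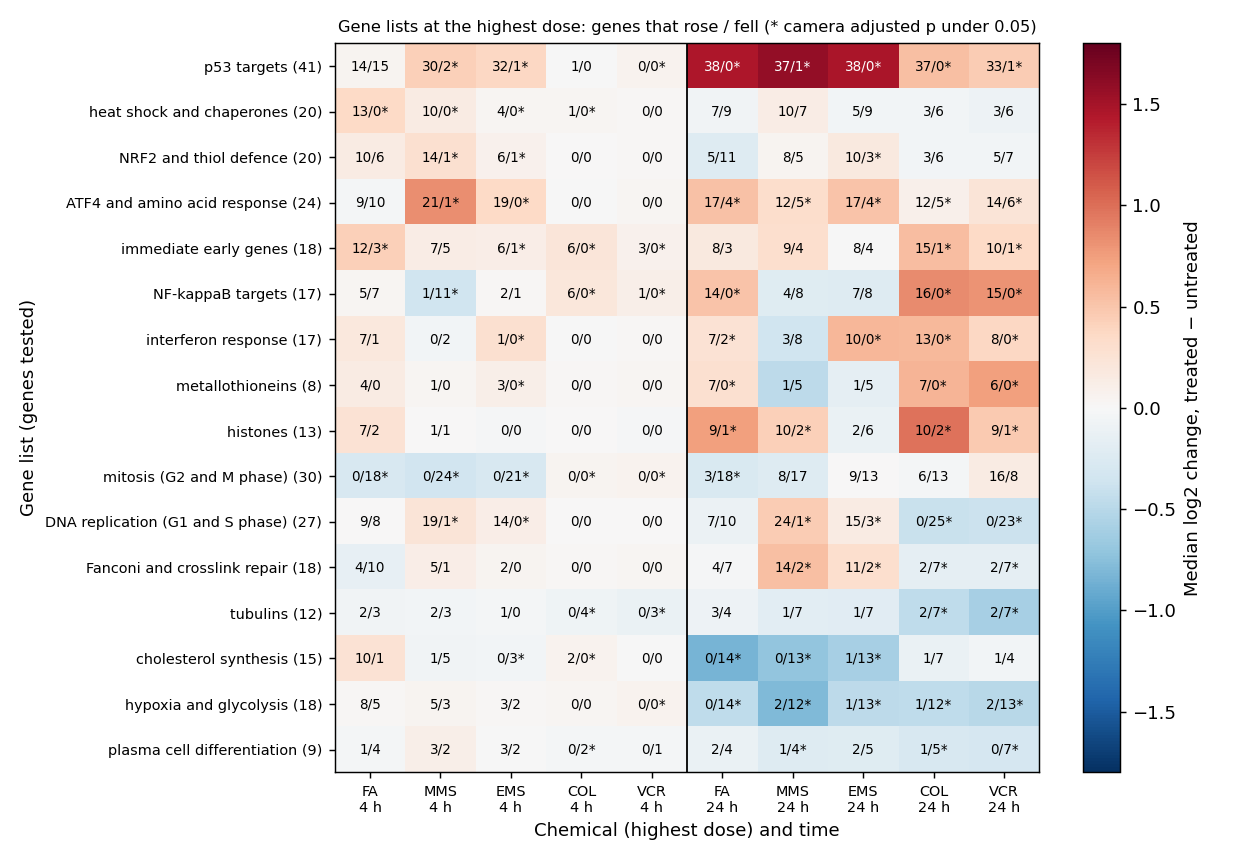
Median log2 change of 16 of the gene lists (colour) at the highest dose of each chemical at 4 h and 24 h, with the number of genes that rose / fell and a star where the camera test passed its threshold with the preset correlation. The p53 targets had 33 to 38 of 41 genes higher at 24 h of every chemical.

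The series sets formaldehyde beside the reference chemicals, compared here at the highest dose of each. These doses were not matched. At 4 h its changes differed from those of MMS for 5578 genes, of EMS for 5899, of colcemid for 6072 and of vincristine for 6085. Heat shock genes rose more with formaldehyde than with EMS in 12 of 20 cases with none lower, than with colcemid in 10 and vincristine in 12 with none lower, and than with MMS in 8 with 4 lower. Of the p53 targets 26 of 41 were lower with formaldehyde than with MMS and 5 higher, and 26 were lower than with EMS and 7 higher. This holds for 200 µM formaldehyde at 4 h, where 32 targets were lower than at 100 µM and 1 higher. The dose of 100 µM was not compared with MMS or EMS. ATF4 genes were lower than with MMS in 19 of 24 cases with 1 higher. Mitosis genes were lower with formaldehyde than with colcemid in 19 of 30 cases and than with vincristine in 20, with none higher. At 24 h the changes differed from those of MMS for 5047 genes, of EMS for 3460, of colcemid for 4584 and of vincristine for 4836, and with 1 experiment left out the last 3 were 1948 to 2456, 2987 to 3677 and 3175 to 3978. Then 36 p53 targets were higher with formaldehyde than with colcemid and 1 lower, and 37 were higher than with vincristine and none lower. Against the clastogens, 7 were higher and 19 lower with formaldehyde than with MMS, and 5 higher and 12 lower than with EMS. Cholesterol synthesis genes were lower with formaldehyde than with colcemid, and than with vincristine, in 14 of 15 cases with none higher. Replication genes were lower than with MMS in 25 of 27 cases with none higher, and higher than with colcemid in 20 with 1 lower. NF-kappaB targets were higher than with EMS in 12 of 17 with none lower and than with MMS in 11 with 1 lower, but 2 were higher and 6 lower than with colcemid and 2 higher and 8 lower than with vincristine. Tubulin genes were higher than with vincristine in 9 of 12 with 1 lower.

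Across the 14023 genes the changes with formaldehyde at 4 h correlated with those of MMS at r = 0.245 ± 0.0547 (SD over pairs of single experiments), EMS at 0.131 ± 0.0918, colcemid at -0.133 ± 0.0716 and vincristine at -0.164 ± 0.142. The last was 0.0294 without experiment 3. At 24 h the values were 0.736 ± 0.0235, 0.797 ± 0.0117, 0.611 ± 0.0159 and 0.516 ± 0.0199. These are of changes averaged over experiments. Single pairs at 24 h lay lower, at 0.654 to 0.727, 0.736 to 0.773, 0.543 to 0.594 and 0.435 to 0.506. The sets of these chemicals share no untreated arrays. Among genes at least 2-fold higher at 24 h, 243 of the 361 of formaldehyde were shared with the 795 of MMS, where independent lists would share 20.5, and 229 were shared with the 399 of EMS, where independent lists would share 10.3. With colcemid 75 were shared (3.24 for independent lists) and with vincristine 51 (2.39). At 4 h 13 of 52 were shared with MMS (0.185) and 3 with EMS (0.0334). Of the 585 genes at least 2-fold lower at 4 h, 11 were shared with MMS (1.21).

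Genes that part the 2 reference classes were chosen without formaldehyde. The mean change of MMS and EMS differed from that of colcemid and vincristine for 3310 genes at 4 h (1525 higher with the clastogens, 1785 lower, 2104 to 2712 in all with 1 experiment left out) and 7659 at 24 h (4193 higher, 3466 lower). Each class held 2 chemicals, at doses that were not matched. The test used the spread between arrays, so these counts do not measure how chemicals of a class vary. Over the 4 h genes the change with 200 µM formaldehyde correlated at 0.369 ± 0.00844 (SD of 3 experiments) with the clastogen mean and -0.206 ± 0.0231 with the aneugen mean, a gap of 0.575 ± 0.0212. These SD vary the formaldehyde experiments alone, with the reference means held fixed. The gap was 0.583 ± 0.121 at 50 µM and 0.887 ± 0.0349 at 100 µM. At 24 h the correlations at 200 µM were 0.789 ± 0.00883 and 0.547 ± 0.0107, a gap of 0.242 ± 0.0178. At 100 µM the gap was -0.108 ± 0.0296, the aneugen value being the higher, and at 50 µM -0.0605 ± 0.0386. A further choice, made after the data were seen, was of class genes whose mean changes with clastogens and aneugens had opposite signs, called or not. Over these, 200 µM formaldehyde had the sign of the clastogens for 69.4% ± 1.21 (SD, n = 3) of 2246 genes at 4 h and 62.0% ± 1.97 of 3786 at 24 h. At 4 h the aneugen sign of most genes was uncertain, since the highest labelled doses gave 128 called genes with colcemid and 35 with vincristine.

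Among markers of other cells, ITGAM, an integrin of myeloid cells, rose at 24 h by 2.96 ± 0.098 with formaldehyde, 2.70 with MMS, 1.92 with EMS, 1.33 with colcemid and 0.85 with vincristine, while HBD was lower, with changes of -1.72 ± 0.10, -2.54, -2.09, -0.79 and -1.30. Only 4 genes each of the monocyte and red blood cell lists were tested, so these are single genes, and S100A8 rose by 0.76 and S100A9 by 0.70 at 4 h of formaldehyde. At most 3 of 8 T and NK cell genes and 3 of 7 epithelial and fibroblast genes were called in any of the 10 highest-dose comparisons. Excision repair and direct reversal genes were divided, with 8 higher and 4 lower of 20 at 4 h of formaldehyde (camera adjusted p = 0.494), XRCC1 at 0.48 and ERCC5 at -0.48, and 6 higher and 8 lower at 24 h (camera adjusted p = 0.426). The unfolded protein response of the endoplasmic reticulum rose in 7 of 16 genes with 1 lower at 4 h of MMS (camera adjusted p = 0.0119, adjusted p = 0.231 with an estimated correlation), led by DNAJB9 (1.04). Of 11 housekeeping genes 4 rose and 5 fell at 24 h of formaldehyde (camera adjusted p = 0.832), with a median and mean of opposite sign.

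Without treatment the 5 sets also differed, in 4700 genes at 4 h and 3634 at 24 h by limma's F test over 15 arrays each (1283 to 5408 and 790 to 3457 with 1 experiment left out). Each treated group was therefore compared with the untreated arrays of its own set. The ACTB 3' minus 5' difference of untreated arrays at 24 h was 0.942 ± 0.0793 (SD) in the MMS set and 0.463 ± 0.0327 in the vincristine set. At the highest dose it changed at 4 h by -0.076 with formaldehyde (0.0424 without the untreated array of experiment 3), 0.078 with MMS, 0.045 with EMS, 0.055 with colcemid and 0.037 with vincristine, and at 24 h by 0.287, 0.938, 0.143, -0.028 and 0.036. The untreated formaldehyde array of experiment 3 at 4 h stood at 0.68, beside a group mean of 0.443 ± 0.207 (SD).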

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

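Of the tests in this part, those of RNA quality for the falls at 4 h of formaldehyde and for the p53 targets at 24 h, both tests of the ACTB difference, the trend of length within bands of brightness and the exchange of whole experiments were chosen only after the results were seen. Groups of 3 arrays were not tested for outlying arrays.

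Several results drew attention because the effect differed between groups. Between 24 h and 4 h the change differed for 7477 genes with 200 µM formaldehyde, 6342 with MMS, 5373 with EMS, 3155 with colcemid and 3147 with vincristine. At 4 h and 24 h it differed for 5578 and 5047 genes between formaldehyde and MMS, 5899 and 3460 between formaldehyde and EMS, 6072 and 4584 between formaldehyde and colcemid, and 6085 and 4836 between formaldehyde and vincristine. Between MMS and EMS the counts were 1029 and 3780, and between colcemid and vincristine 8 and 283. In the fixed panel MDM2 and HMOX1 changed in opposite directions at the 2 times of 200 µM formaldehyde: the difference of 24 h minus 4 h was 2.93 (SE 0.12) for MDM2 and -0.92 (SE 0.16) for HMOX1.

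Other results drew attention as signals in data that no comparison used, the control probe sets, where each of the 3 treated arrays at the highest dose lay above each of the 3 untreated ones, which chance gives in 5% of such comparisons. The 18 hybridization controls, added to each array in fixed amounts, were higher with 200 µM formaldehyde by 0.156 at 4 h (11.32 ± 0.0397 against 11.16 ± 0.1, SD) and by 0.41 at 24 h (11.45 ± 0.043 against 11.04 ± 0.104). The ACTB 3' minus 5' difference was higher by 0.287 at 24 h of formaldehyde, 0.938 at 24 h of MMS, 0.143 at 24 h of EMS and 0.055 at 4 h of colcemid.

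The first pattern weighed was that 585 genes fell and 52 rose at least 2-fold after 4 h of 200 µM formaldehyde. The hybridization controls had a median change of 0.187 where a shift left by the normalization needed a fall. This argues against such a shift at the brightness of the controls, a mean log2 of 11.16 untreated and 11.32 treated. They do not test a shift confined to dimmer signals. The trend with length held within each band of brightness, the weakest rho being -0.135, which argues against brightness as its explanation. Lower RNA quality stays open, since the difference in the ACTB measure was -0.076 with an untreated SD of 0.207 and turned to 0.0424 without the untreated array of experiment 3. The change fell with gene length overall (Spearman rho -0.306), but rho was also -0.431 at 100 µM and -0.283 at 50 µM formaldehyde, where 278 and 0 genes fell 2-fold, and -0.238 for MMS, where 29 did, and the median turned back, from 0.169 up to 5 kb to -0.075 at 100 to 200 kb and then 0.016 at 200 to 500 kb and 0.081 above. Genes at least 2-fold lower had a median length of 71.9 kb, against 5.85 kb for those 2-fold higher and 26 kb for all tested genes. The share that fell 2-fold was 7.07% at 200 to 500 kb and 4.97% above, below the 9.65% at 100 to 200 kb but above the 1.65% up to 5 kb. Whether slowed transcription along genes accounts for any of the falls is a hypothesis that these values do not decide. A rho ignores the size of changes, so the other doses do not decide it either.

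The next pattern was that the p53 targets went both ways at 4 h of 200 µM formaldehyde, 14 higher and 15 lower, and rose in 38 of 41 cases at 24 h. Lower RNA quality was not needed for a rise at 24 h, since at 100 µM, where the ACTB difference was 0.466 ± 0.028 (SD) against 0.481 ± 0.0239, 29 targets rose and none fell, and with colcemid it changed by -0.028 and 37 rose, but a part of it in the rise at 200 µM stays open, since with EMS, at a median of 1.47, the ACTB difference rose too. A trend with length that p53 targets show after any DNA damage was not seen at the strength set in advance. At the highest doses of MMS and EMS the lower of the 2 rho values was -0.208. At 4 h, however, rho among the targets was below 0 at every dose of both, from -0.272 to -0.165. A weaker shared trend therefore stays open. Among the targets the change at 4 h of formaldehyde fell with gene length at rho -0.613, so a fall of long transcripts may have hidden a rise of some targets, as a hypothesis. At 100 µM rho was -0.456 among the targets and 33 of 41 rose, so a trend with length did not by itself prevent a rise. Over all genes 278 fell at least 2-fold at 100 µM and 585 at 200 µM, and rho ignores size, so 100 µM does not decide the hypothesis. Whether p53 itself was active at 4 h of 200 µM stays open.

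The last pattern was the ACTB 3' minus 5' difference at 24 h of 320 µM MMS, 1.88 ± 0.26 (SD) against 0.942 ± 0.0793. Whether lower RNA quality made up changes called there stays open: they correlated with those of EMS at 0.882 across genes, but the ACTB difference rose with EMS too, and a correlation ignores size. Untreated arrays of the MMS set did stand apart, the lowest at 0.755 and the highest of the other sets at 0.68. That the MMS arrays were only prepared apart from the others is argued against by the difference within the set, 0.938, where the largest range over the 3 untreated arrays of a group was 0.381. With the GAPDH control probe sets the difference was 0.118. Whether RNA was degraded in dying cells or after harvest stays open, and no biological explanation was tested.

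For each comparison of a dose with untreated cells, 3 against 3 arrays make 10 splits, too few for a share under 0.05. The real counts, from low to high dose at 4 h and then 24 h, were 115, 5705, 7538, 0, 534 and 6689 for formaldehyde, 225, 1900, 4016, 3995, 6633 and 8197 for MMS, 20, 148, 1346, 3407, 4855 and 7218 for EMS, 0, 9, 128, 5234, 5288 and 5098 for colcemid, and 0, 1, 35, 5248, 5174 and 5011 for vincristine. The highest count of another split was 178 at 160 µM MMS and 24 h, 75 and 304 at 1 and 2 mM EMS and 4 h, and at most 2 in the 27 others. For EMS these counts were above the real ones, which points to a structure of the samples across treatment, and with experiment as a block 47 genes were called at 1 mM. Splits that, like the real one, parted all 3 pairs of an experiment gave 0 genes, and 2 at 320 µM MMS and 24 h. As many genes as in the real split came from 1 of the 10 splits in 24 comparisons, from 2 at 1 and 2 mM EMS and the middle labelled dose of vincristine at 4 h, and from 10 of 10 in the 3 comparisons with 0 genes.

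For the differences between times and chemicals, treated and untreated labels were permuted within each arm in 100 splits. Such a permutation can turn a difference of effects into their sum, so that a split with 1 arm reversed calls many genes. These splits also ignore the pairing by experiment, so they neither exclude chance for a difference nor show it. Brackets give the number of splits as large as the real one, which is included, and the highest other count. The share lay under 0.05 for the times of formaldehyde (2, 7477, equal to the real count), formaldehyde and MMS at 4 h (3, 6718), formaldehyde and colcemid at 4 h (3, 6127) and 24 h (4, 7145), and formaldehyde and vincristine at 4 h (4, 6303). It was 0.05 or more for the times of MMS (9, 7737), EMS (10, 6130), colcemid (10, 4234) and vincristine (13, 3754), formaldehyde and MMS at 24 h (13, 7474), formaldehyde and EMS at 4 h (6, 6284) and 24 h (10, 8122), and formaldehyde and vincristine at 24 h (6, 6041). The same held for MMS and EMS at 4 h (17, 4479) and 24 h (22, 9078) and colcemid and vincristine at 4 h (11, 165) and 24 h (21, 6581), where counts several times the real ones point to the effect that both chemicals of a pair share. With the pairs kept, whole experiments, each a treated array with its untreated array, were moved between the 2 effects compared. This allowed 10 splits, too few for a share under 0.05. The real split alone gave its count in each of the 17 cases (1 of 10). The highest other was 0, or 1 for formaldehyde with colcemid at 4 h and with vincristine at 24 h. A mixed group holds arrays of both effects, which widens its spread, so low counts from the other splits do not speak against chance. The class genes allow 3 splits of the chemicals, also too few, with 3310 real and 476 the highest other at 4 h and 7659 and 2688 at 24 h. Among untreated sets chance was excluded, with 4700 genes and 2 the highest other of 100 splits at 4 h and 3634 and 2503 at 24 h.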

How the results depend on the processing

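The runs without the untreated formaldehyde array of experiment 3 at 4 h and over class genes with mean changes of opposite sign were chosen only after the results were seen. For the other alternatives, a count of genes is given below where it left the range of 1.5 times its value in the report. With 1 experiment left out, groups held 2 arrays, and limma pooled their spread with that of the other groups. Where no other reason is given, the cause was not tested.

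With experiment as a block 41 counts stayed within 1.5 times and 8 moved: 261 for 50 µM formaldehyde at 4 h, 840 for 100 µM at 24 h, 385 for 80 µM MMS at 4 h, 47 for 1 mM EMS at 4 h, 278 for the highest labelled dose of colcemid at 4 h, 3 and 110 for the middle and highest labelled dose of vincristine at 4 h, and 598 for colcemid against vincristine at 24 h. Without the filter on dim genes 46 stayed and 5 moved, with 49 for 50 µM formaldehyde, 140 for 80 µM MMS, 12 for 1 mM EMS, 3 for the middle dose of colcemid and 2 for that of vincristine, all at 4 h. With the mean of probe sets 48 stayed and 3 moved, with 36 for 50 µM formaldehyde and 83 and 21 for the highest doses of colcemid and vincristine, all at 4 h. With quantile normalization repeated 40 stayed and 11 moved. At 4 h these were 461 for 80 µM MMS, 66, 320 and 2062 for EMS, 239 for the highest dose of colcemid, 1, 2 and 53 for vincristine, 1587 for MMS against EMS and 20 for colcemid against vincristine, and 588 for the latter at 24 h. With all arrays in one fit 42 stayed and 7 moved: at 4 h 642 for 50 µM formaldehyde, 442 for 80 µM MMS and 2, 2 and 58 for vincristine, and at 24 h 1 and 1142 for 50 and 100 µM formaldehyde.

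Leaving out each experiment in turn moved 27, 17 and 17 of 51 counts, with fewer samples in each test. Over these runs the counts at 4 h were 1 to 25 for 50 µM formaldehyde (25 without the untreated array of experiment 3 alone, at most 7 without a whole experiment) and 3737 to 5286 for 100 µM. They were 21 to 51, 556 to 1134 and 2377 to 3189 for MMS, 3 to 3, 23 to 36 and 463 to 560 for EMS, 0 to 2 and 22 to 51 for the middle and highest dose of colcemid, and 0 to 0 and 0 to 7 for those of vincristine. At 24 h they were 157 to 201 for 100 µM formaldehyde, 1954 to 2940 for 80 µM MMS and 1826 to 2265 for 1 mM EMS. The differences between times gave 1721 to 2064 genes for colcemid and 1656 to 2359 for vincristine. Differences between chemicals at 24 h gave 1948 to 2456 for formaldehyde and EMS, 2987 to 3677 for formaldehyde and colcemid and 3175 to 3978 for formaldehyde and vincristine. MMS and EMS gave 341 to 510 at 4 h and 2208 to 3263 at 24 h, and colcemid and vincristine 4 to 6 and 93 to 106. The class genes at 4 h numbered 2104 to 2712, and the untreated sets differed in 1283 to 5408 genes at 4 h and 790 to 3457 at 24 h. The counts of 200 µM formaldehyde stayed within 1.5 times in these runs, at 5891 to 6985 at 4 h and 5252 to 5862 at 24 h, as did those of the highest doses of MMS (6786 to 8400), EMS (6193 to 6528), colcemid (3661 to 4159) and vincristine (3464 to 4349) at 24 h.

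Correlations between changes moved by more than their SD without the filter on dim genes, to 0.843 for colcemid and vincristine, 0.590 for formaldehyde and colcemid, 0.777 for formaldehyde and EMS and 0.867 for MMS and EMS at 24 h, and to 0.653 for MMS and EMS at 4 h. With 1 experiment left out they ranged from 0.785 to 0.790 for formaldehyde and EMS at 24 h, from -0.148 to -0.0443 and from 0.594 to 0.611 for formaldehyde and colcemid at 4 h and 24 h, and from 0.678 to 0.698 and from 0.8635 to 0.878 for MMS and EMS. For formaldehyde and vincristine at 4 h the range was -0.243 to 0.0294, a reversed sign without experiment 3. The gap between the correlations of 200 µM formaldehyde with clastogens and aneugens at 4 h was 0.544 with the mean of probe sets, 0.536 with quantile normalization repeated and 0.537 to 0.643 with 1 experiment left out. Over class genes with mean changes of opposite sign the gap was 0.742 at 4 h and 0.445 at 24 h.

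With GAPDH in place of ACTB the 3' minus 5' difference at 24 h was 0.062 for formaldehyde, 0.118 for MMS, 0.043 for EMS and 0.023 for colcemid, and at 4 h of colcemid it reversed to -0.019. Named genes with a reversed sign came with the mean of probe sets: POLB at 4 h of formaldehyde (0.40, then -0.03), MCL1 at 4 h of MMS (0.37, then -0.03) and of EMS (0.18, then 0.00) and VIM at 24 h of vincristine (0.19, then -0.16), where the probe sets of a gene were averaged rather than the brightest taken. These 4 were no longer called in that run. Counting a gene once for each comparison that names it, a further 44 lost their call there, 22 without the filter, 14 with quantile normalization repeated, 12 with all arrays in one fit, 0 with the block, and 105, 84 and 101 with an experiment left out.

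Of 240 list tests, 55 lost their call with an estimated correlation between genes and 185 stayed. With experiment as a block 237 stayed and 3 passed the threshold newly: cholesterol synthesis at 4 h of formaldehyde (adjusted p = 0.0407), hypoxia at the highest dose of colcemid at 4 h (0.0273) and formaldehyde metabolism at 24 h of vincristine (0.0349), whose values with an estimated correlation were 0.686, 0.481 and 0.209. Of the 240, 230 stayed without the filter (10 gained) and with the mean of probe sets (6 gained, 4 lost), 236 with quantile normalization repeated (4 gained), and 231, 233 and 234 with an experiment left out. Signal over background limits dim genes, and those that fewer than 3 arrays showed above 6.183 were not tested.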

Other observations

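The bands of brightness, the run without an untreated formaldehyde array and the choice of genes in the next paragraph came only after the results were seen, whereas the list tests were planned.

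CYP4F3, which oxidizes leukotrienes and other lipids, was among the 2 largest rises at 24 h of each of the 5 chemicals, with 5.58 for formaldehyde, 5.89 for MMS, 4.91 for EMS, 4.30 for colcemid and 3.15 for vincristine, on the log2 scale. HSPA6, a heat shock protein gene, rose by 5.85 ± 0.10 at 24 h of MMS and by 0.55 with EMS. TUBB fell at every labelled dose of both aneugens at 24 h, with -0.82, -0.95 and -1.07 for colcemid and -1.03, -1.36 and -1.39 for vincristine, while TUBA1A rose at 24 h of colcemid by 0.84 ± 0.046. In the lists, NF-kappaB targets rose in 16 of 17 cases at each dose of colcemid and in 15 at each dose of vincristine at 24 h, and metallothionein list genes in 7 of 8 at each dose of colcemid.

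Genes at least 2-fold lower at 4 h of 200 µM formaldehyde made up 1.65% of tested genes up to 5 kb, 1.36% from 5 to 10 kb, 1.39% from 10 to 20 kb, 3.31% from 20 to 50 kb, 8.55% from 50 to 100 kb, 9.65% from 100 to 200 kb, 7.07% from 200 to 500 kb and 4.97% above 500 kb. The share was thus highest between 100 and 200 kb and lower in the 2 longest classes. In order of brightness, rho between length and change was -0.135, -0.187, -0.358, -0.387 and -0.339 in 5 equal bands. Among the p53 targets rho was -0.165 for MMS and -0.208 for EMS at 4 h.

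Some lists of the highest dose not described above also passed the camera test. Fanconi genes rose in 11 of 18 cases with 2 lower at 24 h of EMS (12 and 2 adjusted over the list alone, adjusted p = 0.00466, adjusted p = 0.477 with an estimated correlation) and fell in 7 of 18 with 2 higher at 24 h of colcemid (adjusted p = 0.00213, adjusted p = 0.399 with an estimated correlation) and of vincristine (10 lower and 2 higher adjusted over the list alone, adjusted p = 0.00566, adjusted p = 0.423 with an estimated correlation). Interferon response genes rose in 7 of 17 with 2 lower at 24 h of formaldehyde (adjusted p = 0.0219, adjusted p = 0.51 with an estimated correlation) and in 8 of 17 at 24 h of vincristine (adjusted p = 0.00108, adjusted p = 0.477 with an estimated correlation). Without the untreated formaldehyde array of experiment 3, 48 genes were at least 2-fold higher and 597 lower at 4 h of 200 µM.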
